A study of Mus musculus with 20 samples.

How the data were processed

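RNA was measured by bulk MARS-seq in 20 libraries of cultured thymic ILC2: 12 of IL25R+ cells in 4 groups of 3 (vehicle, IL-25, IL-33 and both cytokines) and 8 of ST2+ cells in 2 groups of 4 (vehicle and IL-33). Per the labels, reads were demultiplexed with bcl2fastq, trimmed with cutadapt, aligned to mouse build mm10 with STAR 2.5.2b, counted per gene with HTSeq and normalised and tested with DESeq2. Whether the counts are of reads or of molecular identifiers, and which filter chose the listed genes, is not stated.

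Each deposited table holds 1 gene per line. The authors deposited counts per library, the signal after division by DESeq2 size factors, regularised log2 values, the log2 fold change of the first-named group over the second, and the p-value with its adjusted form. Those deposited p-values were made by the authors with DESeq2, and their adjusted form controls the FDR. Size factors recomputed from the counts equalled those behind the authors' signal columns. All per-sample columns were mapped to a labelled sample, with 0 left over. Every listed gene had at least 6 counts in its highest library. Of the listed symbols 98.3% (IL25R+) and 98.1% (ST2+) matched GENCODE M21, the annotation used for positions.

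All values in the text were computed from the counts, and the authors' log2 values and p-values were used for 1 check alone. At the authors' adjusted p under 0.05, a base mean above 5 and a 2-fold change, their tables hold 303 genes for vehicle over IL-25, 10 for vehicle over IL-33, 312 for vehicle over both, 52 for IL-25 over both, 277 for IL-33 over both, 229 for IL-25 over IL-33 and 1210 for ST2+ vehicle over IL-33.

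Genes with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total count 15, minimum proportion 0.7), which left 8850 genes in IL25R+ cells, 7626 in ST2+ cells and 8964 in the fit of all 20 libraries. Library sizes were scaled by TMM. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was run with 1 coefficient per group, on all libraries of a table, and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. The SE of a log2 fold change is its absolute value over the square root of the F statistic. Fold changes use edgeR's prior, so a fold against a group with 3 counts or fewer is given as CPM levels or counts, apart from 2 values of Aire that turned direction. The 9 tests were 6 comparisons between the 4 IL25R+ groups, the interaction of the 2 cytokines, IL-33 against vehicle in ST2+ cells, and the difference of the IL-33 effect between the populations.

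The groups, comparisons, filter, tests, 31 gene lists (9 of them markers of other cell types) and the alternatives, apart from those named as added, were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, and with fry; p-values were adjusted over the lists of a comparison with at least 2 measured genes. Counts of list members are given over all genes tested and adjusted over the list alone. Lists can share members: those of type-2 products and of regeneration both hold Il4, Il13, Areg, Lif, Osm, Penk and Hbegf. The rule for named genes took, per comparison, the 10 genes per direction with the largest change among those that passed with a mean of at least 10 CPM (5 per direction for the interaction and the difference), 12 genes always reported and up to 4 members per list; the text names a part of this set. That part was chosen after the values were seen, which departs from the plan. Lists are named in short: glycolysis stands for glycolysis and hypoxia, costimulatory for costimulatory and checkpoint receptors, cholesterol for cholesterol and fatty acid synthesis, immediate early for immediate early and MAPK feedback genes, neuropeptide and lipid receptors for those with adrenergic receptors, NK cells for NK cells and ILC1, mast cells for mast cells, basophils and eosinophils, ILC3 for ILC3 and IL-17 producing cells, and thymic epithelium for thymic epithelium and tuft cells.

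Alternatives were DESeq2 size factors within edgeR, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of the 2 compared groups alone, and each library left out in turn. Alternatives added after the data were seen were the split of the IL25R+ libraries as a term (1 side where Glycam1 was above 10 CPM), IL-33 libraries 1 and 2 of IL25R+ cells left out together, the ST2+ libraries that stood apart left out together, and leave-one-out for list tests and for the correlation. Without IL-33 libraries 1 and 2 the IL-33 group holds 1 library and its spread comes from the other groups. For that fit effect sizes are given without p-values. Other splits of the samples were counted in full for comparisons of 2 groups and in 100 draws for the interaction and the difference.

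The pipeline was tested on simulated data with 200 changed genes, drawn from the fitted means and dispersions. At a 2-fold change the recovered share was 71.6% for IL-25, 73.1% for IL-33 and 74.6% for both against vehicle, 35.8% for the interaction, and 14.9% for IL-33 in ST2+ cells and for the difference between populations. At 4-fold it was 97%, 100%, 97%, 84.8%, 81.5% and 63.6%. Depth ran from 834913 to 1880906 counts per library in IL25R+ cells and from 537999 to 5453444 in ST2+ cells. The Poisson probabilities for Nhlh2 cover counting error alone, and every other test rests on the spread between libraries. No library was removed from the main results. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.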

Results

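Group 2 innate lymphoid cells (ILC2), which make type-2 cytokines without an antigen receptor, were sorted from the thymus of young male wild-type mice. One population was sorted as positive for the IL-25 receptor (IL25R+) and the other as positive for ST2, the IL-33 receptor encoded by Il1rl1 (ST2+). The cells were kept with IL-7 at 10 ng/mL, with a change of medium after 12 h and 24 h more of culture, and then received recombinant cytokine or saline vehicle for 24 h. IL25R+ cells received vehicle, IL-25 (10 ng/mL), IL-33 (10 ng/mL) or both cytokines, with 3 libraries per group and 12 in all. ST2+ cells received vehicle or IL-33, with 4 libraries per group and 8 in all. RNA was counted at the 3' end of transcripts by bulk MARS-seq, a method in which samples are barcoded before they are pooled.

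The IL25R+ table listed 10696 genes and that of ST2+ cells listed 10580, of which 9608 were in both. Total counts in the vehicle libraries of IL25R+ cells were 1423004, 834913 and 1018302. With IL-25 they were 1685290, 1499062 and 1572154, with IL-33 1367999, 1269119 and 1026907, and with both cytokines 1398657, 1880906 and 1652531. In ST2+ cells the vehicle libraries held 1782717, 537999, 593170 and 2736408 counts and the IL-33 libraries 4572981, 1187302, 1628223 and 5453444. The spread between replicates, as edgeR's biological coefficient of variation, was 0.128 in the IL25R+ table and 0.328 in the ST2+ table. The labels do not say whether replicates came from different mice, so every p-value measures the spread between samples. Among the genes named most often, on mouse build mm10 all protein-coding, Il13 lies on chromosome 11 at 53631324 to 53634702, Il5 on chromosome 11 at 53720794 to 53725106, Csf2 on chromosome 11 at 54247271 to 54249667, Il1rl1 on chromosome 1 at 40429570 to 40465415 and Il17rb on chromosome 14 at 29996135 to 30008896. Values per gene are CPM, counts scaled to library size, as mean ± SD, or log2 fold changes ± standard error (SE).

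The IL25R+ libraries fell on 2 sides by Glycam1, Clu and the genes that moved with them. Glycam1, a secreted mucin-like glycoprotein, was at 116 to 439 CPM in the 3 vehicle libraries, IL-33 library 3 and the 3 libraries with both cytokines, and at 0.731 CPM or less in the other 5. Clu, which encodes the secreted chaperone clusterin, was at 24.2 to 353 CPM in the same 7 libraries and at 0.648 CPM or less in the 5. Of 8850 genes tested, 89 were higher in every one of the 7 libraries than in every one of the 5, and 98 were lower. The comparison of IL-25 with vehicle and that of both cytokines with IL-25 lie across these sides, while both cytokines and vehicle lie on one side. Only the IL-33 group holds libraries of both sides. A fit with the split as a term thus estimates it from IL-33 library 3 against IL-33 libraries 1 and 2. With that term, IL-33 against vehicle and both against IL-33 in effect use IL-33 library 3 alone for the IL-33 group. The same split followed the second principal component, which held 17.4% of the variance of the 2000 most variable genes, and the first, with 40.4%, parted the 6 libraries with IL-25 from the other 6.

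**Figure D1:**
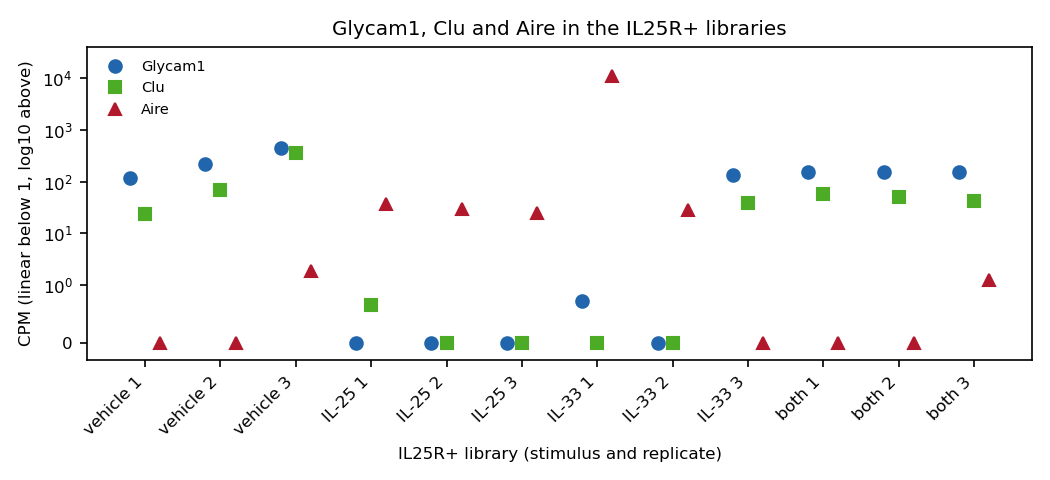
CPM of Glycam1, Clu and Aire in each of the 12 IL25R+ libraries, 1 point per library, on a vertical axis that is linear below 1 and logarithmic above it. Glycam1 was at 116 CPM or more in 7 libraries and at 0.731 CPM or less in 5, and Aire reached 10800 CPM in IL-33 library 1.

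The first comparison asked how IL25R+ ILC2 respond to IL-25, the cytokine that tuft cells release. Il13, a central type-2 cytokine, rose from 23.2 ± 8.96 to 205 ± 92.9 CPM (n = 3 each; log2 change 3.21 ± 0.448, edgeR adjusted p = 3.43e-05). Il1rl1 rose from 9.21 ± 2.23 to 68.2 ± 14.6 CPM, a log2 change of 2.86 ± 0.279 (edgeR adjusted p = 3.36e-07). Gata3, the transcription factor that ILC2 require, rose by 1.0 ± 0.139, and Mki67, a marker of cycling cells, by 3.02 ± 0.334. The largest rises of well-counted genes included Myl4, a myosin light chain, at 4.20 ± 0.283 and Asic3, an acid-sensing ion channel, at 3.70 ± 0.262. Batf, a transcription factor of activated lymphocytes, rose by 2.48 ± 0.196, and Ccl5, a chemokine, by 2.02 ± 0.224. Tcf7 (-0.82 ± 0.124), Bcl6 (-1.66 ± 0.316) and Abcg3 (-1.81 ± 0.279) fell. Il17rb, the IL-25 receptor gene, was at -0.24 ± 0.276 (edgeR adjusted p = 0.601), and Il4 (1.2 ± 0.541), Csf2 (0.01 ± 1) and Il6 (-0.53 ± 0.744) did not pass the test either. By edgeR quasi-likelihood 1325 genes passed, 803 higher and 522 lower, and 278 and 104 of these changed at least 2-fold. The vehicle and IL-25 values did not overlap for 1302 of the 1325, and for 35.3% of all tested genes, where chance gives 10%. The call count was 832 without vehicle library 1, 847 without vehicle library 3 and 645 with the split of the libraries as a term, which kept 357 of the 1325. That term rests on IL-33 library 3 against IL-33 libraries 1 and 2, so values with it carry the noise of 1 library. Il13, Il1rl1, Gata3 and Mki67 passed with that term, while Tcf7 (-0.33, edgeR adjusted p = 0.255) did not. Tnfrsf9 rose by 3.26 ± 0.535 and Cd74 fell by 2.70 ± 0.642; neither passed with the term (2.62, edgeR adjusted p = 0.253, and -0.14, 0.957), nor did Cd74 without vehicle library 3 (0.119). Gapdh was called higher (5.92 ± 1.68, edgeR adjusted p = 0.0197) on IL-25 library 3 alone, and without that library it was at 0.65 (0.875). Gapdh also lost the call without vehicle library 1 (0.0884), 2 (0.0682) or 3 (0.0802), with the term (0.54, 0.947), with the replicate block (0.0599), each by edgeR, and by limma-voom (0.492).

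Proliferation genes moved together with IL-25. Of 18 S phase genes, which act in DNA replication, 17 rose and the other did not pass (18 rose adjusted over the list alone; median log2 change 1.59), with Mcm5 at 1.99 ± 0.216 and Rrm2 at 2.97 ± 0.366. Of 16 G2/M genes 15 rose (16 adjusted over the list alone), with Top2a at 2.36 ± 0.217 and Birc5 at 2.57 ± 0.298. The camera test with its preset correlation gave adjusted p = 2.64e-18 for S phase and 1.51e-13 for G2/M genes, and adjusted p = 0.0309 and 0.0548 with an estimated correlation. Of 8 factors linked to thymus regeneration 5 rose (7 adjusted over the list alone), among them Il13, Osm, Lta and Ltb (camera adjusted p = 8.17e-05, and adjusted p = 0.0416 with an estimated correlation). Il13 and Osm also belong to the list of type-2 products, so the 2 lists are not separate evidence. The unfolded protein response and secretory list had 9 of 19 genes higher, among them Calr and Hspa5, and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00109, and adjusted p = 0.0416 with an estimated correlation). With the split of the libraries as a term 12 S phase and 7 G2/M genes passed, 2 regeneration factors and 3 secretory genes, all higher. The medians with the term were 1.86 for S phase and 2.59 for G2/M genes, against 1.59 and 2.35 without it. Those of the regeneration and secretory lists fell, from 0.962 to 0.762 and from 0.486 to 0.226.

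Effector and activation lists passed with the preset correlation and were lost with an estimated one. Of 9 type-2 cytokines and effector products Il13, Osm, Tnf and Furin rose, and 5 rose adjusted over the list alone (camera adjusted p = 0.000214, and adjusted p = 0.07 with an estimated correlation). Tnf rose by 1.92 ± 0.217 and Furin, a protease that activates precursor proteins, by 1.43 ± 0.199. Among 11 costimulatory receptors 5 rose (7 adjusted over the list alone), with Tnfrsf25 at 2.52 ± 0.378, Icos at 1.94 ± 0.306 and the early activation marker Cd69 at 2.20 ± 0.222 (camera adjusted p = 0.00129, and adjusted p = 0.0718 with an estimated correlation). Of 15 NF-kB targets 7 rose, among them Nfkbiz (1.51 ± 0.212) and Bcl3 (1.32 ± 0.228), and adjusted over the list alone 8 rose and 2 fell (camera adjusted p = 0.00255, and adjusted p = 0.0548 with an estimated correlation). Apoptosis regulators had 5 of 12 higher, with Bcl2l1 at 1.46 ± 0.167 and Cdkn1a at 1.86 ± 0.183, and 1 lower (6 and 1 adjusted over the list alone). Their camera adjusted p was 0.0469, and adjusted p = 0.115 with an estimated correlation. ATF4 targets of amino acid supply had 3 of 10 higher and cholesterol synthesis 3 of 17 (5 and 4 adjusted over the list alone), at camera adjusted p = 0.0387 and 0.0469, and adjusted p = 0.116 and 0.115 with an estimated correlation. The list of MHC class II genes, which present antigen, and costimulatory ligands fell with the split of the libraries: its 4 measured MHC class II genes fell, also adjusted over the list alone, and its 1 measured ligand did not pass, with H2-Aa at -4.66 ± 0.74 (camera adjusted p = 0.00281, and adjusted p = 0.18 with an estimated correlation). Glycam1 and Clu also lie on opposite sides of that split in the 2 groups. With the split as a term Tnf (0.99, edgeR adjusted p = 0.241), Osm (0.86, 0.0786), Lta (0.37, 0.36), Nfkbiz (1.01, 0.157) and Hspa5 (0.21, 0.645) no longer passed, nor did H2-Aa (-1.02, 0.595). The list counts with that term were 2 of 9 type-2 products, 3 costimulatory receptors, 4 NF-kB targets, 2 apoptosis regulators and 2 ATF4 targets higher, and 0 of the MHC class II list lower. In that order the medians of the lists with higher genes were 1.37, 0.66, 0.594, 0.252 and 0.579. Without the term they were 1.29, 0.537, 0.404, 0.192 and 0.425. The median of the MHC class II list went from -2.7 to -0.141 with the term. Without IL-33 library 3, 5 ATF4 targets were higher.

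**Figure D2:**
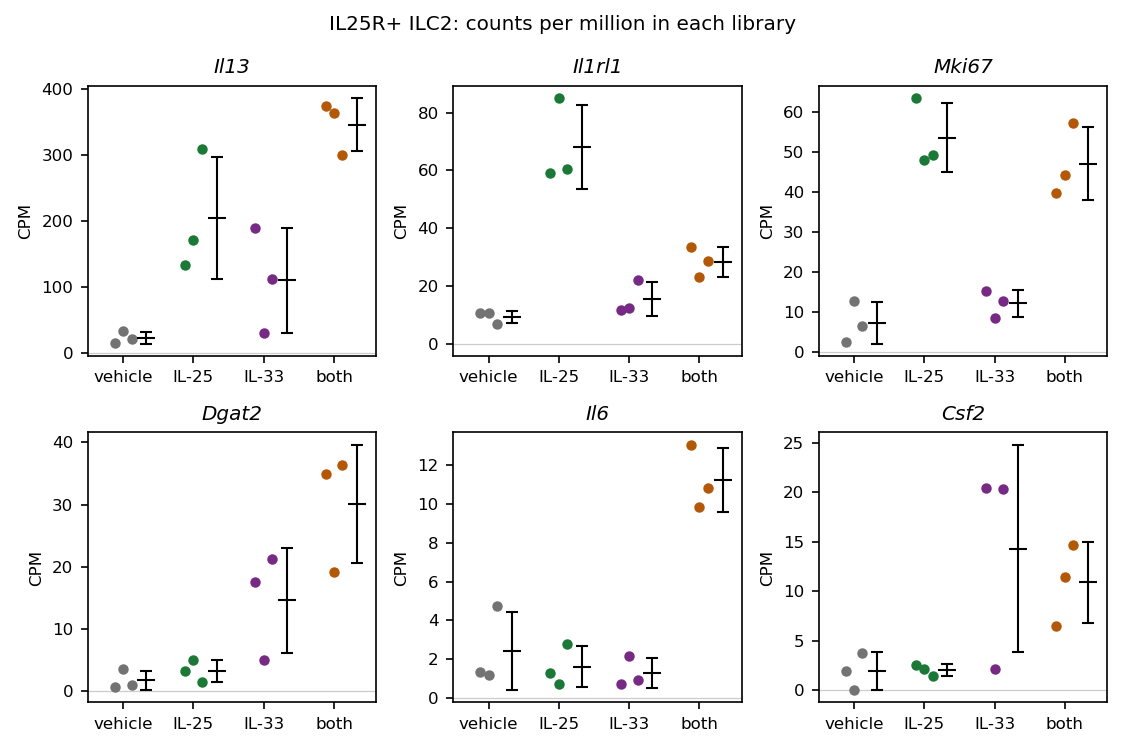
CPM of 6 genes in the 12 IL25R+ libraries by treatment, 1 point per library, with the mean and SD of 3 libraries. Il1rl1 and Mki67 were highest with IL-25 alone, while Dgat2 and Csf2 were higher in the groups that received IL-33.

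IL-33 was given to IL25R+ cells to ask whether this population also responds to the other alarmin. Il13 rose from 23.2 ± 8.96 to 110 ± 79.4 CPM (n = 3 each; log2 change 2.32 ± 0.47, edgeR adjusted p = 0.0399), and its 3 IL-33 libraries held 189, 30.4 and 112 CPM. Dgat2, which makes triglycerides, rose from 1.71 ± 1.57 to 14.6 ± 8.48 CPM (3.2 ± 0.675, edgeR adjusted p = 0.0455), and Rpph1, the RNA of ribonuclease P, rose by 2.90 ± 0.572. Uqcrb, a subunit of respiratory complex III, fell by 0.82. Csf2, which encodes GM-CSF, was at 2.73 ± 0.712 (edgeR adjusted p = 0.103), and it passed without IL-33 library 2 (0.00187). It also passed with the split as a term (0.0349), which in effect compares IL-33 library 3 alone with vehicle. Il1rl1 (0.69 ± 0.348), Mki67 (0.90 ± 0.424), Gata3 (0.09 ± 0.145), Il17rb (-0.28 ± 0.283), Il4 (0.08 ± 0.639) and Il6 (-0.80 ± 0.798) did not pass. By edgeR quasi-likelihood 21 genes passed, 16 higher and 5 lower, with 8 and 3 changed at least 2-fold. The 2 groups did not overlap for 18 of the 21, and for 14.5% of all tested genes, where chance gives 10%. Aire was called higher on IL-33 library 1, at 10800 CPM against 28.2 and 0 in libraries 2 and 3, with 2 counts in the vehicle group. The direction of Aire was turned with the split as a term and without IL-33 libraries 1 and 2, at 0 counts in IL-33 library 3 and 2 with vehicle. Its call was lost without any 1 of the vehicle or IL-25 libraries or IL-33 library 1 (edgeR adjusted p = 0.0511 to 0.362), without a filter (0.0633) and by limma-voom (0.699). Hnrnph1 (0.84 ± 0.142) and Eef1g (0.69 ± 0.117) rose, both at edgeR adjusted p = 0.0288.

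The number of IL-33 calls changed with single libraries. The count was 10 without vehicle library 1, 0 without vehicle library 2 or 3, 3 without IL-25 library 1, 0 without IL-25 library 2 or 3, 9 without IL-33 library 1, 105 without IL-33 library 2, 151 without IL-33 library 3 and 8 without library 3 with both cytokines, by edgeR each time. The 21 calls compare with 1069 genes at an unadjusted p under 0.05, 33 by DESeq2 and 10 by limma-voom. By edgeR the count was 2 without a filter, 8 at a mean of at least 10 CPM and 1 with these 2 groups alone. It was 212 with the split as a term, a fit that in effect sets IL-33 library 3 alone against vehicle. Il13 and Dgat2 each lost the call without any 1 of the 3 vehicle or 3 IL-25 libraries, IL-33 library 1, or library 1 or 3 with both cytokines (edgeR adjusted p = 0.0506 to 0.362 for Il13). Without an IL-25 library or library 1 or 3 with both, which lie outside the comparison, their log2 changes stayed at 2.32 to 2.33 and 3.2 to 3.21, so these losses are of a p near the threshold. Without IL-33 library 1 Il13 was at 1.65, and without vehicle library 2 Dgat2 was at 4.06. They did not pass by limma-voom either (0.188 and 0.184), without a filter (0.0704 each by edgeR) or at a mean of at least 10 CPM (0.0569 and 0.0629). Rpph1 lost it without any 1 of the vehicle or IL-25 libraries, up to 0.362, and Uqcrb without vehicle library 2 or 3, any 1 of the IL-25 libraries or library 3 with both, also up to 0.362. Hnrnph1 lost its call without any 1 of the vehicle libraries or IL-25 library 2 or 3 (0.0547 to 0.115) and Eef1g without vehicle library 2 or 3 or IL-25 library 2 or 3 (0.0582 to 0.226), and both with the 2 groups alone (0.264 and 0.274), each by edgeR. Among the fixed lists, 2 of 9 type-2 products rose, and 4 adjusted over the list alone (camera adjusted p = 0.00606, and adjusted p = 0.247 with an estimated correlation). Without IL-33 library 1 the count was 0, and with the split as a term, in effect IL-33 library 3 against vehicle, it was 4. None of the 18 S phase genes passed alone, also adjusted over the list alone, at a median of 0.36 (camera adjusted p = 0.00368, and adjusted p = 0.368 with an estimated correlation). With the term 2 S phase genes rose. None of the 5 genes of MHC class II and costimulatory ligands passed over all genes and 4 fell adjusted over the list alone, while 4 fell over all genes without IL-33 library 3, with 2 of the 3 IL-33 libraries on the side of the split without Glycam1 (camera adjusted p = 0.00014, and adjusted p = 0.247 with an estimated correlation).

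Both cytokines together were compared with vehicle to measure the joint response, and these groups lie on one side of the split. Gapdh, chosen after its values were seen, was at 3.8 to 10.5 CPM in the vehicle libraries and 811 to 913 CPM in those with both, and at 1410 CPM in IL-25 library 3 and 924 CPM in IL-33 library 2 against 8.04 to 12.8 CPM in their replicates. It was called higher with both (6.75 ± 1.67, edgeR adjusted p = 0.00801), but not without vehicle library 1 (0.0537) or by limma-voom (0.075). Il13 rose from 23.2 ± 8.96 to 346 ± 40 CPM (n = 3 each; log2 change 3.97 ± 0.439, edgeR adjusted p = 1.38e-06). Dgat2 rose to 30.1 ± 9.52 CPM (4.26 ± 0.586), Asic3 by 4.16 ± 0.254, Myl4 by 3.99 ± 0.287, Wfdc21 by 4.43 ± 0.498 and Ebi3, a cytokine subunit of IL-27 and IL-35, by 3.98 ± 0.476. Lad1 was at 0.781 CPM with vehicle, 2 counts in that group, and at 20.5 ± 8.06 CPM with both. Il6 rose by 2.21 ± 0.52 (edgeR adjusted p = 0.0055), Csf2 by 2.39 ± 0.722 (0.0264), Il1rl1 by 1.59 ± 0.307, Gata3 by 0.86 ± 0.139 and Mki67 by 2.84 ± 0.338. Il15, which sustains lymphocytes, fell by 2.20, and Clec12a, an inhibitory lectin receptor, fell by 2.01. Il17rb (-0.68 ± 0.285, edgeR adjusted p = 0.114) and Il4 (0.70 ± 0.569) did not pass, though Il17rb passed without vehicle library 1 (0.0488). By edgeR quasi-likelihood 1384 genes passed, 794 higher and 590 lower, with 310 and 96 changed at least 2-fold. Values did not overlap for 1362 of the 1384, and for 36.3% of all tested genes, where chance gives 10%. Without vehicle library 1 the count was 779 and Il6 no longer passed (edgeR adjusted p = 0.0613), nor did it by DESeq2 (0.0532). Csf2 lost its call without vehicle library 1 (0.118), vehicle library 2 (0.0882), or library 2 (0.0647) or 3 (0.096) with both, each by edgeR, and by limma-voom (0.0566). With 1 library left out its change ran from 1.99 to 3.07 and that of Il6 from 1.81 to 3.07.

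With both cytokines 7 lists passed under either correlation in camera. Of 9 type-2 products 8 rose, also adjusted over the list alone (median 2.13, camera adjusted p = 6.7e-08), with Tnf at 2.0 ± 0.215 and Furin at 1.46 ± 0.198. All 18 measured S phase genes rose, also adjusted over the list alone (camera adjusted p = 4.35e-21), with Rrm1 at 1.96 ± 0.214 and Mcm5 at 2.13 ± 0.214. NF-kB targets rose in 7 of 15 cases (9 adjusted over the list alone; 1.23e-06), with Relb at 1.76 ± 0.234 and Nfkbia, the feedback inhibitor, at 0.93 ± 0.127. Of 21 ribosome biogenesis and Myc genes 5 rose and 1 fell (10 and 1 adjusted over the list alone; 0.000331), with Srm at 0.90 ± 0.134 and Nop56 at 0.65 ± 0.122, and 9 rose with the split as a term or without IL-33 library 3. The secretory list had 8 of 19 higher (9 adjusted over the list alone; 0.000213), with Calr at 1.07 ± 0.118 and Hspa5 at 0.82 ± 0.143. ATF4 targets had 4 of 10 higher (5 adjusted over the list alone; 0.00093), with the serine pathway enzymes Shmt2 at 0.90 ± 0.15 and Phgdh at 0.94 ± 0.167. The regeneration list had 5 of 8 higher, also adjusted over the list alone (0.000347). G2/M genes rose in 14 of 16 cases (15 adjusted over the list alone), with Top2a at 2.16 ± 0.218 (camera adjusted p = 1.72e-11, and adjusted p = 0.0508 with an estimated correlation).

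Further lists in the joint response passed with the preset correlation alone. Costimulatory receptors had 4 of 11 higher, also adjusted over the list alone, with Cd69 at 3.04 ± 0.209 (camera adjusted p = 0.00867, and adjusted p = 0.112 with an estimated correlation). Cholesterol synthesis had 5 of 17 higher, also adjusted over the list alone (0.0155, and adjusted p = 0.055 with an estimated correlation). Of 4 chemokines 2 rose, also adjusted over the list alone, with Ccl5 at 2.60 ± 0.223 (0.0318, and adjusted p = 0.193 with an estimated correlation). The glycolysis and hypoxia list, which includes Gapdh, had 5 of 19 higher and 1 lower (8 and 1 adjusted over the list alone; 0.0318, and adjusted p = 0.181 with an estimated correlation). Neuropeptide and lipid receptors had 2 of 6 higher, also adjusted over the list alone, the prostaglandin receptors Ptger4 at 1.71 ± 0.181 and Ptgir at 1.21 ± 0.219 (0.0416, and adjusted p = 0.112 with an estimated correlation). Among 8 T cell markers 4 fell, also adjusted over the list alone, with Cd3d at -0.70 ± 0.159 and Themis at -0.73 ± 0.167 (0.00867, and adjusted p = 0.139 with an estimated correlation). Irf4 (3.37 ± 0.59) and Batf (2.72 ± 0.195), transcription factors of activated lymphocytes, rose, as did Bcl2l1 (1.70 ± 0.164). MHC class II genes and costimulatory ligands had 0 of 5 past the edgeR test, also adjusted over the list alone (camera adjusted p = 0.524).

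**Figure D3:**
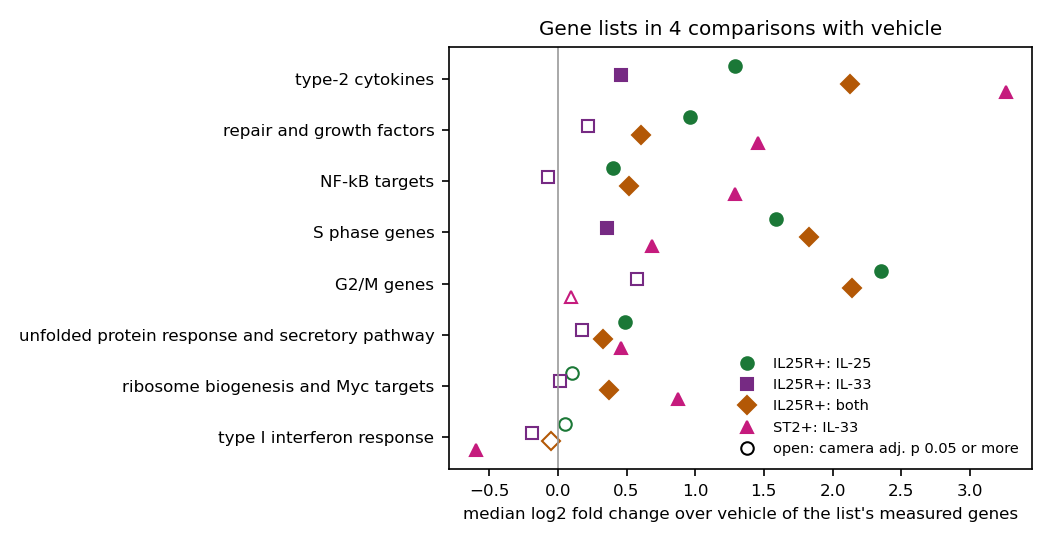
Median log2 fold change of 8 gene lists in the 4 comparisons with vehicle, 1 symbol per list and comparison, open where camera's adjusted p with the preset correlation was at or above the threshold. The S phase median was 1.59 with IL-25, 0.36 with IL-33 and 1.83 with both cytokines in IL25R+ cells, and 0.69 with IL-33 in ST2+ cells.

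Adding IL-33 to IL-25 was examined by comparing both cytokines with IL-25 alone, which lies across the split. Irf4 was higher by 4.43 ± 0.635 (30.95 ± 15 against 1.37 CPM, n = 3 each), Dgat2 by 3.19 ± 0.468, the chemokine gene Ccl3 by 2.97 ± 0.491, Il6 by 2.74 ± 0.523 and Cd69 by 0.84 ± 0.157. Lad1 was at 0.448 CPM with IL-25, 2 counts in that group, and at 20.5 ± 8.06 CPM with both. Il1rl1 was lower with both, at 28.35 ± 5.22 against 68.2 ± 14.6 CPM (log2 difference -1.27 ± 0.22, edgeR adjusted p = 0.00301), as were S100a11 (-1.76 ± 0.262), Ppia (-1.46 ± 0.227) and Gpx4 (-1.30 ± 0.201). Il13 (0.76 ± 0.329, edgeR adjusted p = 0.218), Csf2 (2.38 ± 0.671, 0.0547), Il4 (-0.50 ± 0.456), Gata3 (-0.13 ± 0.129), Mki67 (-0.19 ± 0.229) and Il17rb (-0.43 ± 0.28) did not pass. Il13 passed without IL-33 library 2 (edgeR adjusted p = 0.0443), and Csf2 passed without IL-33 library 1 (0.027), 2 (0.00772) or 3 (0.0222). By edgeR quasi-likelihood 278 genes passed, 120 higher and 158 lower, with 41 and 29 changed at least 2-fold, and none of the 278 overlapped between groups (26.4% of all tested genes did not, where chance gives 10%). With the split as a term 5 genes passed, 1 of them among the 278, and none of the named genes did, as with Irf4 (2.02, edgeR adjusted p = 0.592), Dgat2 (2.28, 0.283) and Il1rl1 (-2.16, 0.118). The count was 99, 120 and 99 without IL-25 library 1, 2 and 3, 84, 80 and 166 without library 1, 2 and 3 with both, 444 without IL-33 library 1, 620 without IL-33 library 3, and 870 when only these 2 groups were fitted.

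Of 26 lists tested for both against IL-25, 7 passed with the preset correlation and 0 of 26 with an estimated one in camera. Chemokines had 3 of 4 higher (4 adjusted over the list alone; camera adjusted p = 7.04e-05, and adjusted p = 0.0922 with an estimated correlation). The list of MHC class II genes and costimulatory ligands had 4 of 5 higher, the 4 of MHC class II, which follow the split, also adjusted over the list alone, with H2-Aa at 4.88 ± 0.706 (0.000174, and adjusted p = 0.172 with an estimated correlation). Fibroblast and endothelial markers follow it too and had 2 of 4 higher, also adjusted over the list alone (0.000333, and adjusted p = 0.157 with an estimated correlation), and Glycam1 was at 0 CPM in every IL-25 library. NF-kB targets had 2 of 15 higher and ribosome biogenesis 2 of 21 (4 and 2 adjusted over the list alone), both at 0.00452, and adjusted p = 0.0922 with an estimated correlation. Type-2 products had 2 of 9 higher (3 adjusted over the list alone; 0.0462, and adjusted p = 0.278 with an estimated correlation), and T cell markers 1 of 8 lower (2 adjusted over the list alone; 0.0166, and adjusted p = 0.278 with an estimated correlation). With the split as a term 0 genes of these 7 lists passed the edgeR test. Without IL-33 library 1 or 3, 4 type-2 products were higher, and without IL-33 library 3, 3 T cell markers were lower.

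Both cytokines against IL-33 alone measured what IL-25 adds. Spib, an Ets family transcription factor, was higher by 3.93 ± 0.309, Asic3 by 3.37 ± 0.223, Irak3, a brake on IL-1 family signalling, by 3.21 ± 0.322 and Cd69 by 3.14 ± 0.205 (edgeR adjusted p = 5.87e-10). Il13 was higher by 1.65 ± 0.348, Il6 by 3.01 ± 0.565, Tnf by 1.97 ± 0.209, Ccl5 by 2.60 ± 0.22, Mki67 by 1.94 ± 0.289 and Gata3 by 0.77 ± 0.136, while Clec12a (-2.47 ± 0.381) and Hes1 (-1.58 ± 0.311) were lower. Il1rl1 (0.90 ± 0.274, edgeR adjusted p = 0.0259) lost its call without IL-33 library 1 (0.74, 0.102) or 2 (0.77, 0.111), or library 1 (0.77, 0.0971) or 3 (0.89, 0.0688) with both. It was at 0.33 without IL-33 libraries 1 and 2, and at 0.91 (edgeR adjusted p = 0.0546) with these 2 groups alone. Csf2 (-0.34 ± 0.486), Il4 (0.62 ± 0.546) and Il17rb (-0.40 ± 0.287) did not pass. By edgeR quasi-likelihood 1519 genes passed, 822 higher and 697 lower, with 279 and 123 changed at least 2-fold; 1403 did not overlap, and 31.6% of all genes did not, where chance gives 10%. Of the lists, 16 passed with the preset correlation and 3 with an estimated one in camera: S phase (17 of 18 higher, 18 adjusted over the list alone), NF-kB targets (8 of 15, 9 adjusted over the list alone) and ribosome biogenesis (6 of 21, 8 adjusted over the list alone), each at adjusted p = 0.0165. S phase genes were higher in 11 cases with the split as a term, and G2/M genes in 14 of 16 and in 4 with the term. The G2/M median was 1.76, 1.5 with the term and 1.67 without IL-33 libraries 1 and 2, which leaves 1 IL-33 library. That of S phase genes was 1.46, 1.18 and 1.24 in the same order. Mcm3 was at 1.39 ± 0.163, Top2a at 1.53 ± 0.198, and the receptors Ptger4 and Calcrl at 1.65 ± 0.175 and 1.30 ± 0.277. The count was 946 and 933 without library 2 and 3 with both, 1000 by DESeq2, 982 with these 2 groups alone and 649 with the split as a term (465 of the 1519 kept). With that term the IL-33 group is in effect IL-33 library 3 alone. With the term Hes1 (-0.87, edgeR adjusted p = 0.194), Clec12a (-1.23, 0.149), Calcrl (0.89, 0.17) and Il1rl1 (0.34, 0.617) did not pass, and by DESeq2 Il13 had adjusted p = 0.051 and Il1rl1 0.0646.

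IL-33 and IL-25 were also compared directly. With IL-33 the log2 difference was -2.17 ± 0.25 for Il1rl1 (edgeR adjusted p = 4.49e-06), -2.12 ± 0.287 for Mki67, -0.91 ± 0.136 for Gata3, -1.89 ± 0.211 for Tnf, -2.29 ± 0.218 for Cd69 and -2.79 ± 0.138 for Pou2f2, a lymphocyte transcription factor. Csf2 (2.72 ± 0.665, edgeR adjusted p = 0.00856), Dgat2 (2.13 ± 0.536) and Tcf7 (0.90 ± 0.124) were higher with IL-33, and the first pair lost the call without IL-25 library 3 (2.51, 0.0513, and 1.78, 0.0666) and by limma-voom (0.124 and 0.0593). Jun was higher too (1.52 ± 0.338), but at 0.63 without IL-33 libraries 1 and 2. Il13 (-0.89 ± 0.353, edgeR adjusted p = 0.1), Il4 (-1.12 ± 0.519), Il6 (-0.27 ± 0.817) and Il17rb (-0.04 ± 0.277) did not pass, though Il13 passed without IL-33 library 1 (-1.57, 0.00166). Of 18 S phase genes 16 were lower (17 adjusted over the list alone; camera adjusted p = 7.5e-16, and adjusted p = 0.0496 with an estimated correlation), with Mcm5 at -1.42 ± 0.2. G2/M genes were lower in 14 of 16 cases (15 adjusted over the list alone; 3.37e-13, and adjusted p = 0.07 with an estimated correlation), with Top2a at -1.73 ± 0.197. Without IL-33 libraries 1 and 2, which leaves 1 IL-33 library, the medians were -1.12 for S phase and -1.56 for G2/M genes. In the main fit they were -1.22 and -1.78. In all 10 lists passed with the preset correlation. By edgeR quasi-likelihood 1223 genes passed, 485 higher and 738 lower, with 92 and 238 changed at least 2-fold; 1163 did not overlap, and 28.8% of all genes did not, where chance gives 10%. The count was 806 and 634 without IL-25 library 2 and 3, and 732 with these 2 groups alone.

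The interaction term asked whether the effect of both cytokines departed from the sum of the single effects on the log2 scale. Il1rl1 departed from that sum by -1.96 ± 0.411 (edgeR adjusted p = 0.0152; n = 3 per group, with means of 9.21, 68.2, 15.4 and 28.35 CPM for vehicle, IL-25, IL-33 and both). It no longer passed without vehicle library 3 (-1.79, 0.0583), without library 2 with both (-1.83, 0.0517) or with the split as a term (-3.40 ± 0.812, 0.054), so the departure was as large or nearly so and the adjusted p crossed the threshold. Pcgf1 departed by -2.01 ± 0.436 (edgeR adjusted p = 0.0189), and lost the call without vehicle library 3 (-1.90, 0.0583), IL-25 library 1 (-1.96, 0.0572) or library 2 with both (-1.57, 0.0517), and with the term (-1.03, 0.667). Il13 was at -1.56 ± 0.583 (edgeR adjusted p = 0.161) and passed without IL-33 library 2 (-2.03, 0.0091). Il6 was at 3.54 ± 0.994 (0.0617 by edgeR, and 0.0469 without IL-33 library 3). Gata3 (-0.22 ± 0.194), Mki67 (-1.09 ± 0.482), Csf2 (-0.35 ± 1.13), Il4 (-0.58 ± 0.791) and Il17rb (-0.15 ± 0.397) did not pass. H2-Aa, at 6.77 ± 0.903, follows the split of the libraries, as do Glycam1 and Clu, which were near 0 CPM with IL-25 and at 24.2 CPM or more in every vehicle library. By edgeR quasi-likelihood 208 genes passed, 92 higher and 116 lower, with 68 and 62 departing at least 2-fold. With the split as a term 14 passed, 0 of them among the 208, where 1516 had an unadjusted p under 0.05 without the term and DESeq2 called 176. The count was 133, 88 and 68 without vehicle library 1, 2 and 3, 57, 86 and 102 without IL-25 library 1, 2 and 3, 701 without IL-33 library 3, and 104, 45 and 114 without library 1, 2 and 3 with both. Of the lists 5 passed with the preset correlation, with MHC class II genes and costimulatory ligands at 4 of 5 higher, the 4 of MHC class II (also adjusted over the list alone, and 0 with the split as a term), camera adjusted p = 9.15e-07, and adjusted p = 0.164 with an estimated correlation. Fibroblast and endothelial markers, which follow the split too, had 2 of 4 higher (camera adjusted p = 0.000665) and chemokines 1 of 4 (0.000143), and 0 of either with the term. NF-kB targets and ribosome biogenesis, with 0 genes called, passed at 0.0455 each. With an estimated correlation each of these lists was at 0.164 too.

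In ST2+ ILC2, IL-33 was compared with vehicle to describe the response of the population sorted on its receptor. Il13 rose from 336 ± 235 to 9439 ± 4400 CPM (n = 4 each; log2 change 4.80 ± 0.594, edgeR adjusted p = 0.000864). Il5, the eosinophil growth factor, rose from 14.97 ± 6.68 to 721.5 ± 552 CPM (5.48 ± 0.728). Il9 was at 0.222 ± 0.263 CPM with vehicle, 2 counts in that group, and at 102 ± 32.9 CPM with IL-33 (edgeR adjusted p = 2.16e-05). Areg, an epidermal growth factor family ligand of tissue repair, rose from 3.56 ± 2.75 to 71.8 ± 58.9 CPM (4.05 ± 0.924, edgeR adjusted p = 0.0137), and Csf2 rose from 18.99 ± 13.6 to 288 ± 148 CPM (3.74 ± 0.508). Dgat2 rose from 11.04 ± 4.87 to 578 ± 163 CPM, Asic3 by 5.41 ± 0.477, Pla2g7 by 5.19 ± 0.491, Rpph1 by 5.20 ± 0.434, Lad1 by 5.85 ± 0.789 and Il6 by 3.26 ± 0.558. Tnfrsf8, which encodes CD30, was at 1 count in the vehicle group and at 71.5 ± 63.9 CPM with IL-33. The chemokine receptor Ccr2 fell from 78.96 ± 37.8 to 0.673 ± 0.323 CPM (-7.03 ± 0.614, edgeR adjusted p = 0.00023), Cpne7 fell by 5.56 and Tmem273 by 4.45 on the log2 scale. Il17rb fell from 84.1 ± 28.8 to 15.9 ± 4.33 CPM (-2.37 ± 0.301, edgeR adjusted p = 0.000931). Il1rl1 (-0.79 ± 0.332, edgeR adjusted p = 0.126), Gata3 (-0.50 ± 0.236), Klrg1 (0.16 ± 0.329), Il4 (-0.67 ± 0.392) and Mki67 (-0.46 ± 0.415) did not pass.

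**Figure D4:**
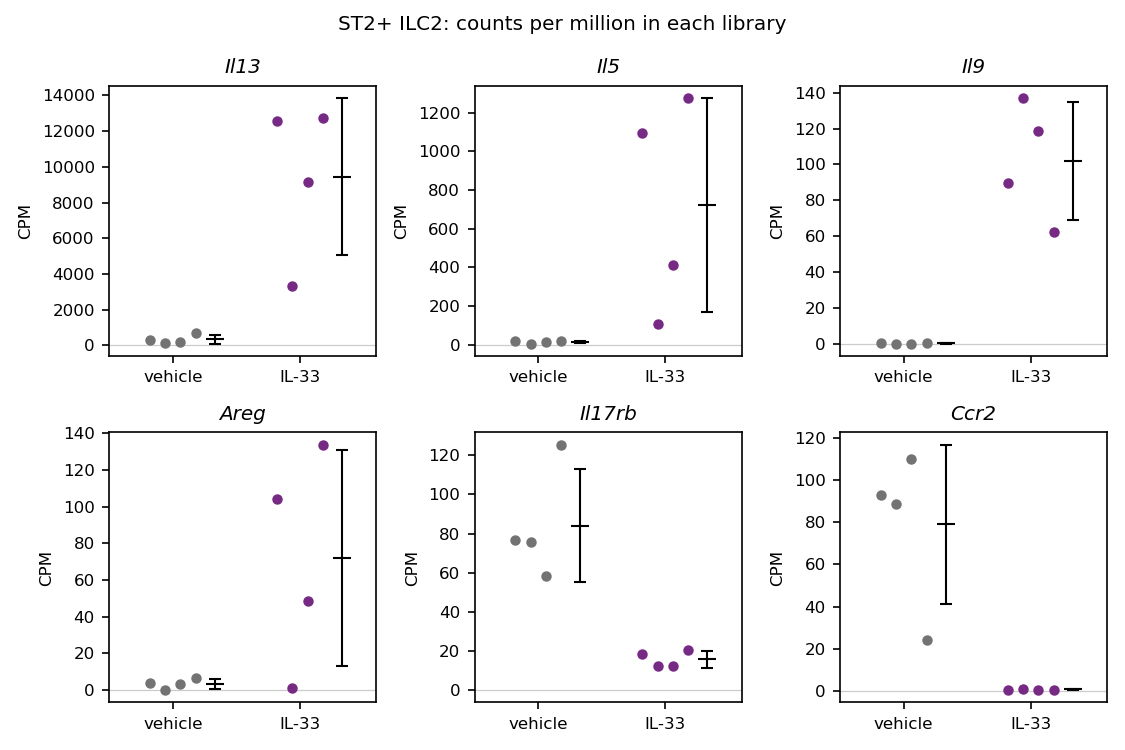
CPM of 6 genes in the 8 ST2+ libraries by treatment, 1 point per library, with the mean and SD of 4 libraries. Il13 rose from a mean of 336 to 9439 CPM and Ccr2 fell from 78.96 to 0.673 CPM.

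IL-33 library 2 stood apart from the other ST2+ libraries, at -54.6 on the second principal component (24.7% of the variance of the 2000 most variable genes). It held 3331 CPM of Il13, 109 of Il5 and 1.11 of Areg, where the other 3 held 9129 to 12730, 410 to 1274 and 48.7 to 134. By edgeR quasi-likelihood 1262 genes passed in the ST2+ comparison, 650 higher and 612 lower, with 426 and 512 changed at least 2-fold. Values did not overlap for 1108 of the 1262 and for 22% of all 7626 tested genes, where chance gives 2.86%. The count was 2581 without IL-33 library 2, with 1260 of the 1262 kept, and 736, 737, 619 and 693 without vehicle library 1, vehicle library 2, IL-33 library 1 and IL-33 library 4. Areg lost its call without vehicle library 1 (4.02, edgeR adjusted p = 0.0539) and by limma-voom (0.173). Gbp4 fell by 2.55 ± 0.614 (edgeR adjusted p = 0.0179), a call lost without vehicle library 1 (-1.78, 0.0864) or IL-33 library 1 (-2.17, 0.0601) or 4 (-2.35, 0.066). Without vehicle library 3 and IL-33 library 2 together 2526 genes passed.

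**Figure D5:**
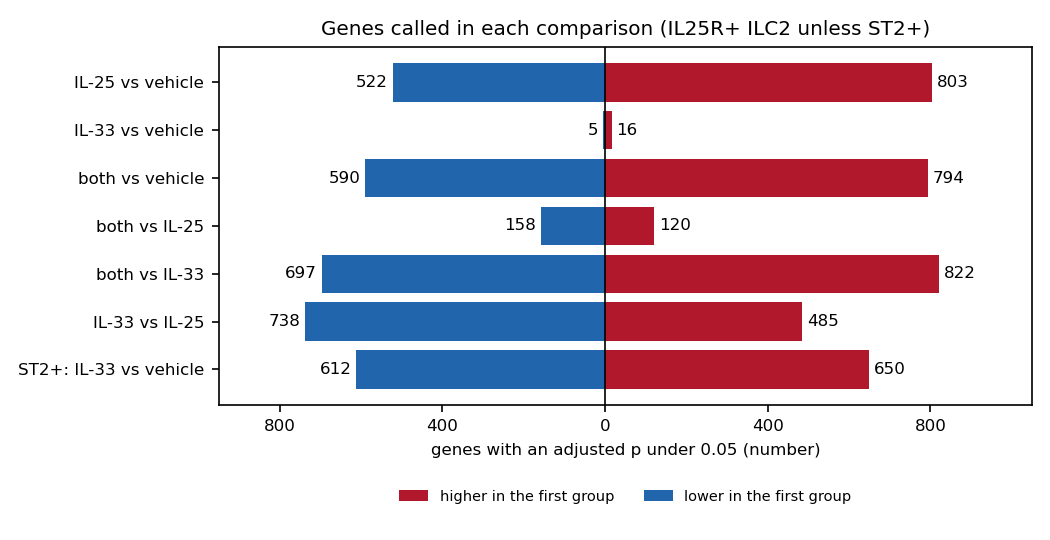
Numbers of genes called higher and lower by edgeR quasi-likelihood in 7 comparisons between groups, as bars from 0. The smallest total was 21, for IL-33 against vehicle in IL25R+ cells.

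Lists in ST2+ cells that passed under either correlation were those of type-2 products and NF-kB targets. Of 15 type-2 products 13 rose, also adjusted over the list alone (median 3.26; camera adjusted p = 2.26e-07, and 0.0334 with an estimated correlation), with Furin at 2.98 ± 0.28 and Penk, the enkephalin precursor, at 4.10 ± 0.563. Of 14 NF-kB targets 8 rose (12 adjusted over the list alone; 2.76e-06, and 0.0354 with an estimated correlation), with Nfkbia at 1.78 ± 0.188, Bcl3 at 2.30 ± 0.26 and Nfkb2 at 1.28 ± 0.255. Ribosome biogenesis and Myc genes rose in 8 of 20 cases (11 adjusted over the list alone; 2.65e-06, and adjusted p = 0.0938 with an estimated correlation), with Srm at 1.98 ± 0.222, Nop16 at 1.64 ± 0.245 and Odc1 at 1.45 ± 0.271. S phase genes rose in 6 of 18 cases (8 adjusted over the list alone; 0.000513, and adjusted p = 0.207 with an estimated correlation) and G2/M genes in 1 of 17, also adjusted over the list alone (0.59). Immediate early genes rose in 4 of 9 cases (5 adjusted over the list alone), with Nr4a1 at 2.86 ± 0.426 and Junb at 1.69 ± 0.293 (0.00086, and adjusted p = 0.207 with an estimated correlation). The glycolysis and hypoxia list had 5 of 18 higher (6 adjusted over the list alone), with Pkm at 1.33 ± 0.263 and the lactate exporter gene Slc16a3 at 1.92 ± 0.347 (0.00976, and adjusted p = 0.193 with an estimated correlation). ATF4 targets had 3 of 10 higher (5 adjusted over the list alone), with Shmt2 at 1.52 ± 0.278 and Atf4 at 1.11 ± 0.173 (0.00475, and adjusted p = 0.193 with an estimated correlation). The secretory list had 4 of 18 higher and 1 lower (5 and 1 adjusted over the list alone), with Calr at 1.44 ± 0.28 (0.0124, and adjusted p = 0.207 with an estimated correlation). Without IL-33 library 2, 14 ribosome biogenesis, 8 glycolysis, 5 ATF4, 8 secretory and 2 G2/M genes rose, and without vehicle library 3, 2 glycolysis genes and no G2/M gene did.

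Regeneration-linked factors in ST2+ cells had 8 of 14 higher and 1 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.0322, and adjusted p = 0.193 with an estimated correlation), and Pdgfb rose by 4.10 ± 0.959. Pdgfb lost its call without vehicle library 2 (3.88, edgeR adjusted p = 0.0525) and by limma-voom (0.127). Interferon response genes had 3 of 11 lower (5 adjusted over the list alone), with Irf7 at -1.54 ± 0.274 (0.0203, and adjusted p = 0.373 with an estimated correlation). Cytokine and alarmin receptors had 5 of 14 lower and 2 higher (6 and 2 adjusted over the list alone), with Ifngr1 at -1.70 ± 0.216 (0.0329, and adjusted p = 0.276 with an estimated correlation). Costimulatory receptors had 3 of 11 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.364), with Tnfrsf9 at 3.87 ± 0.5. ILC2 identity genes had 2 of 17 higher, Irf4 (4.60 ± 0.544) and Batf (2.84 ± 0.266), and 1 lower (2 and 4 adjusted over the list alone; 0.589). JAK-STAT targets had 4 of 15 higher and 2 lower, also adjusted over the list alone (0.343), and apoptosis regulators 2 of 11 higher and 2 lower (4 and 2 adjusted over the list alone; 0.609), with Pim2 at 3.15 ± 0.344, Bcl2l1 at 1.81 ± 0.221 and Bcl2 at -2.21 ± 0.438. Of 15 migration genes 1 rose and 2 fell (1 and 4 adjusted over the list alone; 0.169), and Itgae, an integrin that binds epithelial cadherin, fell by 2.56. Without IL-33 library 2, 5 interferon response genes fell, 5 costimulatory receptors rose, and 4 apoptosis regulators rose and 4 fell; 2 regeneration factors and 2 identity genes fell. Without vehicle library 3, 2 JAK-STAT targets and 0 receptors rose, and 0 identity genes fell.

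Whether the IL-33 effect differs between the populations was tested on all 20 libraries in one fit, as ST2+ minus IL25R+. The populations come in separate tables, so a difference between them cannot be told apart from one between tables or runs. An offset of a table that is the same with vehicle and IL-33 cancels. The fit takes 1 spread per gene over both tables, although their coefficients of variation were 0.128 (IL25R+) and 0.328 (ST2+). The effect was more positive in ST2+ cells for Gstm1, a glutathione transferase (4.97 ± 0.529, edgeR adjusted p = 1.32e-05), Asic3 (4.71 ± 0.622), Irak3 (4.25 ± 0.804), Il6 (4.06 ± 0.952), Tnf (2.36 ± 0.536) and Furin (2.20 ± 0.353). Ccr2 (-6.42 ± 1.05), Il17rb (-2.0 ± 0.429), Ifngr1 (-1.93 ± 0.255), Gbp4 (-2.47 ± 0.544), Cd3g (-1.85 ± 0.413), Lck (-1.90 ± 0.452), Ifit2 (-2.71 ± 0.775) and Irf7 (-1.30 ± 0.349) had a more negative effect in ST2+ cells. Ifit2 lost its call without vehicle library 2 or 3 or IL-33 library 1 or 3 of IL25R+ cells, or IL-33 library 1 or 4 of ST2+ cells (-2.22 to -2.60, edgeR adjusted p = 0.0506 to 0.0981), and Irf7 without vehicle library 1 (-1.25, 0.053) or IL-33 library 3 (-1.06, 0.0689) of IL25R+ cells. Abcg3 passed as more negative, at 1 count in the IL-33 group of ST2+ cells, except without ST2+ vehicle library 1 (edgeR adjusted p = 0.0637) and by limma-voom (0.0652). Tnfrsf8 passed as more positive, at 1 count in the ST2+ vehicle group, except without vehicle library 2 (0.157) or 3 (0.0501) of IL25R+ cells, by edgeR. For Il13 the difference was 2.56 ± 0.812 (edgeR adjusted p = 0.0439), and it was lost in 14 of 20 fits that left out 1 library, at adjusted p up to 0.128 and differences of 2.11 to 2.83, and by limma-voom (0.0589). These 14 were the 3 vehicle libraries, IL-25 library 2, IL-33 libraries 2 and 3 and the 3 libraries with both in IL25R+ cells, and vehicle libraries 1, 2 and 3 and IL-33 libraries 1 and 4 in ST2+ cells. Il6 lost its call without vehicle library 3 of IL25R+ cells (3.22, edgeR adjusted p = 0.113). Il5, with 1 count in the vehicle group of IL25R+ cells, Csf2 (0.96 ± 1.29), Il1rl1 (-1.41 ± 0.558, edgeR adjusted p = 0.102), Klrg1, with 2 counts in that group, Gata3 (-0.52 ± 0.292), Il4 (-0.63 ± 0.747) and Mki67 (-1.27 ± 0.719) did not pass, nor did Il9 (edgeR adjusted p = 0.0542). Il9 passed by DESeq2 (0.00222), by limma-voom (0.0218), and without IL-33 library 3 (0.0383) or library 1 (0.0145), 2 (0.00471) or 3 (0.0434) with both of IL25R+ cells, or IL-33 library 2 of ST2+ cells (0.0489). Klrg1 passed without IL-33 library 3 of IL25R+ cells (0.049) or IL-33 library 2 of ST2+ cells (0.0183), and Il1rl1 without vehicle library 4 of ST2+ cells (0.0339). By edgeR quasi-likelihood 1032 of 8964 genes passed, 418 more positive and 614 more negative in ST2+ cells, with 295 and 565 differing at least 2-fold. Without IL-33 library 2 of ST2+ cells 2002 passed, with all 1032 kept, and 1859 without the 3 libraries that stood apart.

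NF-kB targets and ribosome biogenesis genes differed in their IL-33 effect between the populations, which are also separate tables, under either correlation. Of 15 NF-kB targets 9 were more positive in ST2+ cells (11 adjusted over the list alone; camera adjusted p = 3.15e-07, and 0.00393 with an estimated correlation), with Bcl3 at 2.83 ± 0.411, Bcl2l1 at 1.90 ± 0.288 and Nfkbia at 1.69 ± 0.213. Of 21 ribosome biogenesis and Myc genes 10 were more positive (12 adjusted over the list alone; 5.01e-08, and 0.0148 with an estimated correlation), with Srm at 1.92 ± 0.268 and Odc1 at 1.71 ± 0.391. Type-2 products had 4 of 12 more positive, and 6 more positive and 1 more negative adjusted over the list alone (0.00339, and adjusted p = 0.0993 with an estimated correlation). Interferon response genes had 5 of 14 more negative (7 adjusted over the list alone; 0.025, and adjusted p = 0.29 with an estimated correlation), 3 without IL-33 library 1 and 2 without IL-33 library 3 of IL25R+ cells. S phase genes had 0 of 18 past the edgeR test, also adjusted over the list alone (camera adjusted p = 0.253). IL-33 library 2 of ST2+ cells and the split of the IL25R+ libraries both enter this comparison.

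The IL-25 and IL-33 effects in IL25R+ cells were correlated across 8582 genes, which are not independent replicates, with Pearson's r = 0.522 and Spearman's rho = 0.431. Because both effects share the vehicle libraries, simulated data without any effect gave a mean r of 0.532, with a range of 0.506 to 0.556 over 20 simulations. The covariance was 0.126 against 0.042 in the simulations. IL-25 and both cytokines, which also share the vehicle libraries, had 493 genes called higher in each and 250 called lower in each, where independent calls would give 72 and 34.8. Of 745 genes called in both of these comparisons, 743 had the same direction. These 2 effects correlated at r = 0.739 across 8850 genes, which are not independent replicates, and simulated groups without any effect that shared the vehicle libraries gave a mean r of 0.55 over 5 simulations. The numbers for independent calls take no account of the shared libraries.

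Markers of other cell types were few among the measured genes. T cell markers had 0 of 8 past the edgeR test with IL-25 (camera adjusted p = 0.442). In ST2+ cells 2 of 6 T cell markers fell with IL-33, also adjusted over the list alone, namely Cd3g (-1.69 ± 0.379) and Lck (-1.82 ± 0.43), at camera adjusted p = 0.0322, and adjusted p = 0.276 with an estimated correlation. Lck lost its call without vehicle library 2 (-1.76, edgeR adjusted p = 0.0551). Epcam (-2.31 ± 0.446) and Ly75 (-1.90 ± 0.348), the 2 measured markers of thymic epithelium, both fell in ST2+ cells, also adjusted over the list alone (camera adjusted p = 0.0203, and adjusted p = 0.207 with an estimated correlation). Fibroblast and endothelial markers in IL25R+ cells follow the split of the libraries and had 1 of 4 higher and 2 lower with IL-25 (camera adjusted p = 0.114). NK cell markers had 2 of 5 higher and 1 lower with IL-25 (0.711) and 1 of 2 lower with IL-33 in ST2+ cells (0.16), both by camera. With the split as a term 2 T cell markers fell with IL-25, 0 fibroblast and endothelial markers did and 1 NK cell marker rose; without vehicle library 3 the NK cell marker of ST2+ cells did not pass. ILC3, B cell, myeloid and mast cell markers had 1 measured gene each in IL25R+ cells, erythroid markers 0, and myeloid markers 0 in ST2+ cells, and of mast cell markers in ST2+ cells 1 of 2 rose (camera adjusted p = 0.328), and 0 of 4 without vehicle library 3. With IL-25 the 1 ILC3 (0.44), 1 B cell (0.58) and 1 mast cell marker (0.72) rose by edgeR and the myeloid marker (-0.57) did not pass; with the split as a term the ILC3 marker alone passed. In ST2+ cells the 1 ILC3 marker fell (-0.93) and the 1 B cell marker rose (0.87) with IL-33, the latter not without vehicle library 3. Of 5 ILC3 markers measured without IL-33 library 2, 2 rose and 2 fell.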

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

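The tests of the split of the IL25R+ libraries, of lower interaction genes under added cells and of the interaction with the split as a term were chosen only after the result was seen. A sample was singled out when its gap to the nearest replicate exceeded 0.83 of the range of its group of 4, which chance does in about 1 of 20 groups: 6 of 110 group values did so, and 5.5 would by chance.

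The interaction of IL-25 and IL-33 had 208 genes and coincides with the split of the libraries, since IL-25 alone lies wholly on one side and vehicle and both cytokines on the other. If the 2 sides differ, IL-33 library 3, which lies with vehicle, should deviate from its replicates in the direction of the calls. Of the interaction calls 74% did so, just under the bound of 75% set for it, against 56.9% of uncalled genes. Of the calls for both against vehicle, which lie on one side, 66.4% did so too, and 50.2% of those for IL-25 against vehicle. Library 1 and library 2 gave 33.7% of the interaction calls each, but deviations of 3 replicates are tied, so these are not separate comparisons. This explanation stays open. Cells of stroma or antigen-presenting type in the 7 libraries are argued against as the whole source, because 62 genes were lower by at least 1 on the log2 scale and 79.3% of the higher genes had a mean of at least 10 CPM in the 5 libraries. A joint effect of the cytokines cannot be told apart from the split: with the split as a term 14 genes passed and 0 of the 208, 173 of the 208 kept their direction, the median change fell from 1.11 (SE 0.253) to 0.609 (SE 0.482), and simulated 2-fold interactions were recovered in 0% of cases with that term. In 3 of 100 splits of the samples as many genes passed. The highest other split gave 1811 genes and parted the libraries with IL-25 from those without, so these splits also follow the response to IL-25, and whether chance gives the interaction stays open; the next gave 262.

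IL-33 library 2 of ST2+ cells lies apart from the other ST2+ libraries. Its top gene took 2.18% of counts, against 1.37% to 1.39% in its replicates and 1.53% to 2.06% in the vehicle libraries. With transcript length its deviation had a Spearman correlation of -0.0729. From shortest to longest in 4 groups its medians were 0.208, 0.105, -0.0673 and 0.139, so a higher rate of short transcripts stays open. Lower depth is argued against by a ratio of 1.62 between its deviation and the highest other after thinning to its depth. Its deviation correlated with GC content at 0.292, against -0.25 to 0.2 in the other 7 libraries. Ribosomal protein genes took 33% of its counts, against 18.3% to 24.9% in its replicates and 26.6% to 29.5% in the vehicle libraries. A bias by GC content or in library preparation was not tested further and stays open. A weaker response to IL-33 stays open too: the mean correlation of its deviation with the response of the other libraries was -0.304, between the bounds of -0.5 and -0.2 set for it. In ST2+ cells 1 of 35 splits, the smallest share possible, gave as many as 1262 genes (highest other 0), which argues against chance.

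Tnfrsf8 had 0.37 CPM in ST2+ vehicle library 4 and 0 in the other 3, which is 1 count. Bcl2l1 was at 107 CPM in vehicle library 4 of ST2+ cells against 66.8 to 70.5 in the others. Junb had 138 CPM in ST2+ vehicle library 3 and 74 to 76.1 in the others. Epcam was at 3.34 CPM in ST2+ IL-33 library 2 against 1.28 to 1.61 in the others. Gbp4 was at 40.4 CPM in ST2+ vehicle library 1 against 10.7 to 13.8 in the others, and its call was lost without that library.

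The IL-33 effect differed between ST2+ and IL25R+ cells for 1032 genes by the edgeR quasi-likelihood test of the difference itself, with 712 to 2002 when 1 library was left out. Population and table coincide here, so a cause in either cannot be told apart. In 3 of 100 splits as many genes passed. The highest other split gave 1350 genes, kept the real ST2+ groups and took vehicle libraries 1 and 3 and IL-33 library 3 as one IL25R+ group, and the next gave 1111. These splits follow the ST2+ response, so they do not settle whether chance gives a difference between the populations. Named genes with a more positive effect in ST2+ cells, as log2 differences, were Gstm1 (4.97), Asic3 (4.71), Irak3 (4.25), Il6 (4.06), Bcl3 (2.83), Il13 (2.56), Tnf (2.36), Furin (2.20), Srm (1.92), Bcl2l1 (1.90), Odc1 (1.71) and Nfkbia (1.69). Named genes with a more negative effect were Ccr2 (-6.42), Gbp4 (-2.47), Il17rb (-2.0), Ifngr1 (-1.93), Cd3g (-1.85), Lck (-1.90), Ifit2 (-2.71) and Irf7 (-1.30). Tnfrsf8 and Abcg3 passed too. Tnfrsf8 had 1 count in the ST2+ vehicle group and a mean of 71.5 CPM with IL-33, and Abcg3 had 1 count in the ST2+ IL-33 group and a mean of 5.41 CPM with vehicle.

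For the 6 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real counts were 1325, 21, 1384, 278, 1519 and 1223 for IL-25, IL-33 and both against vehicle, both against IL-25, both against IL-33 and IL-33 against IL-25, and the highest other counts by edgeR were 0, 4, 0, 0, 0 and 3.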

How the results depend on the processing

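Fits with the split as a term, with libraries that stood apart left out together, and leave-one-out for lists and for the correlation were chosen only after the data were seen. Under the settings not named here (DESeq2 size factors, the replicate block, no filter, a 10 CPM minimum, DESeq2 and limma-voom where not listed) every count of genes stayed within 1.5 times its main value. Same-number libraries had a mean correlation of -0.0136 in IL25R+ cells, against 0.00696 for other pairs, and of 0.149 in ST2+ cells, against -0.0491. In ST2+ cells 2 of 4 same-number pairs were over 0.1 and 4 of 8 libraries correlated best with their own number, so pairing there stays open; the numbers were not treated as pairs. With the block the counts were 1246, 31, 1338, 220, 1392, 1148 and 160 for the 6 comparisons of IL25R+ groups and the interaction, in the order of the report, and 1241 for ST2+ cells; the block was not fitted for the difference between populations. With the split as a term the counts were 645 for IL-25, 212 for IL-33, 5 for both against IL-25, 649 for both against IL-33 and 14 for the interaction. That term rests on IL-33 library 3 against 1 and 2. Thus 212 and 649 in effect use 1 IL-33 library, as do counts without IL-33 replicates 1 and 2. For IL-33 against vehicle in IL25R+ cells no filter gave 2, the 10 CPM minimum 8, DESeq2 33, limma-voom 10, the 2 groups alone 1, and leaving out IL-33 replicates 1 and 2 together 303. The 2 groups alone gave 870 for both against IL-25, 982 for both against IL-33 and 732 for IL-33 against IL-25; both against IL-33 had 1000 by DESeq2 and 768 without IL-33 replicates 1 and 2. Without vehicle replicate 3 and IL-33 replicate 2 the ST2+ count was 2526, and without all 3 libraries that stood apart the difference between populations had 1859.

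Leaving out 1 library gave 832 to 1718 genes for IL-25, 0 to 151 for IL-33, 779 to 1738 for both, 80 to 620 for both against IL-25, 933 to 1928 for both against IL-33, 634 to 1252 for IL-33 against IL-25, 45 to 701 for the interaction, 619 to 2581 for ST2+ cells and 712 to 2002 for the difference. List calls with the preset correlation were 11, 3, 14, 7, 16, 10, 5, 13 and 9 in that order, and 3, 0, 7, 0, 3, 1, 0, 2 and 2 with an estimated correlation. With 1 library left out they ranged over 8 to 11, 1 to 8, 12 to 15, 7 to 8, 13 to 16, 4 to 10, 3 to 7, 9 to 15 and 7 to 11. The correlation of the IL-25 and IL-33 effects was 0.48 with the 10 CPM minimum and 0.467 to 0.59 with 1 library left out. Aire turned in the IL-33 comparison, to -2.88 with the split as a term and -2.88 without IL-33 replicates 1 and 2, fitted values at 0 counts in IL-33 library 3 and 2 with vehicle, which depend on the prior count. Of 1474 named-gene values under other settings 1390 kept direction and call, 71 lost and 11 gained the call and 2 turned; of 2325 with 1 library left out 2208 kept both, 100 lost and 17 gained the call and 0 turned. The named genes were chosen after such values were seen. Over every gene of the naming rule, all settings together, values that kept direction and call were 1723 of 1872 for IL-25, 144 of 395 for IL-33, 1841 of 1908 for both, 548 of 767 for both against IL-25, 1909 of 2129 for both against IL-33, 1760 of 2000 for IL-33 against IL-25, 314 of 476 for the interaction, 1285 of 1434 for ST2+ cells and 1568 of 1795 for the difference. List counts were recomputed for the split as a term and for the libraries that stood apart, not for every library. Fewer libraries and fewer genes tested are part of these settings by construction; apart from that the cause was not tested.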

Other observations

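The 3 tests of the Aire reads and the test of the shared direction were chosen only after the result was seen. The response of IL25R+ cells to both cytokines and that of ST2+ cells to IL-33, which share no library, had 228 genes called higher in each and 155 called lower in each, where independent calls would give 60.1 and 33.8, which is 3.79 and 4.59 times as many. Genes called higher or lower in IL25R+ cells and the other way in ST2+ cells were 12 and 1. Without IL-33 library 2 of ST2+ cells the shared calls were 331 and 224 against 126 and 68.2, ratios of 2.62 and 3.28, the opposite calls were 28 and 8, and r was 0.412. Of 396 genes called in both comparisons 383 had the same direction, and the log2 changes correlated across 7154 genes, which are not independent replicates, at Pearson's r = 0.44 and Spearman's rho = 0.448. Il13, Dgat2, Asic3, Il6, Csf2, Irf4, Batf, Furin and Lad1 rose in both. IL-25 alone gave r = 0.308 with the ST2+ response and 273 of 300 shared calls in the same direction, and IL-33 alone gave r = 0.203 and 8 of 8. A response common to both populations is a candidate explanation: on mean log CPM the correlation was 0.453, the highest of 35 splits of the ST2+ libraries (highest other 0.415), at the smallest exact p these splits can give, 0.029. Without the S phase, G2/M and ribosome biogenesis lists it was 0.457 against 0.418.

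Lists without a call are listed here for IL-25 against vehicle in IL25R+ cells, by edgeR and camera. ILC2 identity genes had 4 of 17 higher and 2 lower (adjusted p = 0.327), cytokine and alarmin receptors 5 of 13 higher and 2 lower (0.0907), JAK-STAT targets 4 of 16 higher and 2 lower (0.387) and neuropeptide and lipid receptors 2 of 6 higher (0.261). Chemokines had 1 of 4 higher and 1 lower (0.637), immediate early genes 1 of 12 higher (0.637), glycolysis 5 of 19 higher and 2 lower (0.0917), ribosome biogenesis 4 of 21 higher and 2 lower (0.159), lipid uptake 1 of 7 higher (0.291), interferon response 0 of 15 higher and 1 lower (0.838), migration 4 of 15 higher and 1 lower (0.144) and thymic epithelium 0 of 3 (0.954). With the split of the libraries as a term the genes higher were 2 of identity, 1 of receptors, 2 of JAK-STAT, 0 of neuropeptide and lipid receptors, 2 of glycolysis, 1 of ribosome biogenesis, 1 of migration and 2 of immediate early genes; 1 immediate early gene was lower. Without IL-33 library 1, 3 of 13 immediate early genes were lower, and without IL-33 library 3, 1 was.

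Aire, the regulator of tissue antigens in thymic epithelium, was at 10800 CPM in IL-33 library 1 of IL25R+ cells, 1.08% of its counts, at 24.3 to 36.3 CPM in the IL-25 libraries, 28.2 in IL-33 library 2, 0 in IL-33 library 3 and at most 1.9 in the 7 libraries on the other side of the split. Thymic epithelial cells are argued against as its source, since the MHC class II genes of such cells reached 5.84 CPM at most in that library, and a response to IL-33 is argued against by the 28.2 CPM at most in its replicates. Reads of that library misassigned to the other 4 on its side at one share for every gene would give 24.7 counts of Nhlh2, which was at 1550 CPM there, and 1 was found. The Poisson probability, 4.78e-10, covers counting error alone and takes counts as independent molecules, which the labels do not settle. With the expected count divided by 1.94, the variance over mean of the Aire counts in these 4 libraries and a ratio added after the data were seen, it was 3.99e-05. Beside Aire, 7 genes were nearly confined to that library among the 12, among them Nhlh2, Foxc1 and Hoxb7. The source of these reads was not found.

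Gapdh, chosen after its values were seen, was at 811 to 1410 CPM in 5 IL25R+ libraries (IL-25 library 3, IL-33 library 2 and the 3 with both cytokines) and at 3.8 to 12.8 CPM in the other 7, which include the 3 with vehicle. In ST2+ cells it was at 729 to 2460 CPM in vehicle libraries 1 and 4 and IL-33 libraries 1, 2 and 3, and at 28.9 to 35.5 CPM in vehicle libraries 2 and 3 and IL-33 library 4. In IL25R+ cells this coincides with the comparison of both cytokines with vehicle. Whether library pools differed in mapping or in the counting of this gene was not tested, since reads were not used here.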
